A study of Mus musculus with 2 samples.

How the data were processed

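Calvarial osteoblasts, the bone-forming cells grown out from the skull vault of newborn mice, were profiled on Affymetrix mouse expression arrays. The 2 samples were 1 array of osteoblasts labelled as from mice that carry a Dlk1 transgene (Col1-Dlk1) and 1 array labelled as wild-type osteoblasts, both on the C57Bl/6 background. Cells came from mice 4 to 5 days old and were released with trypsin and then collagenase, per the labels' protocols. Per the series' design text, 3 separate cultures of each genotype were combined and put on the array. Each array is therefore a pool with no replicate, and the spread between cultures or animals cannot be computed. Dlk1-positive cells of the transgenic cultures were enriched by fluorescence-activated sorting, per the labels' protocols. Whether the wild-type cells also passed through the sorter is not given in the sources used here.

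The deposited values are probe-set intensities on a linear scale, made by the authors with Affymetrix Expression Console 1.1.1, per the submitters' processing notes. The algorithm, the background correction and the scaling target are not given in the sources used here. No detection calls were used, since the table holds intensities alone. The mean intensity after trimming 2% of values at each end was 150.06 on the array labelled Col1-Dlk1 and 150.07 on the array labelled wild type, so the arrays share a common scale. The table holds 22690 probe sets, 64 of them Affymetrix controls. The array name in the design text differs from the platform of the probe annotation, and the annotation was joined by probe-set ID. Of the 22626 other probe sets, 20380 name 1 gene, 691 name several and 1555 name none here. Of 20393 single-gene annotations, 20364 matched a gene ID of the RefSeq gene table, which gave current symbols. No genome build is named for the values, so no coordinates are given.

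Intensities were converted to log2(intensity + 10.96), the pseudocount being the 25th percentile of all values. Probe sets of 1 gene were averaged on that scale, which gave 12393 genes, 4956 of them with several probe sets. Printed intensities of such genes are those averages turned back to the linear scale. Differences are the array labelled Col1-Dlk1 minus the array labelled wild type, and every fold is on the log2(intensity + pseudocount) scale, which understates the difference of dim genes. A gene passed the level threshold when the higher of its values reached 42.8, the median of all values. It was called higher or lower when it also differed by at least 2-fold. With 1 array per genotype there is no test, no p-value and no standard error, and a call is a rule of size that compares these arrays, not the genotypes.

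Gene lists for osteoblast function, signalling, lineage and the markers of other cells were fixed before the data were examined. So were the level and fold thresholds, the alternatives and the rule for named genes, but not the alternatives and lists identified as added. That rule takes Dlk1, the 12 called genes with the largest difference in each direction whose probe sets all differ the same way, and up to 4 level-passing members of each list with the largest difference. Predicted genes and clone names are passed over, which concerned 2 higher and 1 lower gene among all calls. Other list members that are named below were chosen after their values were seen. The median difference of each list was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. This percentile describes these arrays only. Intervals of list medians are 95% order-statistic intervals over genes, which are not independent replicates. List members without a single-gene probe set were not analysed here. Members below the level threshold count as measured but cannot be called at any fold.

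The steps were tested on simulated data in which a second array was made from the wild-type one, with a log2 SD of 0.25 per probe set. Among 12393 genes, 200 were set 4-fold higher or lower, all drawn from those at or above the level threshold on the wild-type array. All the raised genes (100%) and all the lowered genes (100%) were called, and 0 other genes were. Of 40 random lists of 20 unchanged genes, 39 fell between percentiles 5 and 95. The simulated noise was chosen near the spread between probe sets below and holds no biological variation. Changes of 4-fold lie far above that noise and the 2-fold rule, so this checked the steps and not genes near the rule. Raised genes that start below the level threshold were not simulated. Alternatives covered the scaling (median centring, quantile normalization, loess with a span of 0.3), the pseudocount, the level filter, the fold, the handling of probe sets and, added after seeing the data, lists without macrophage and osteoclast markers. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.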

Results

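The data are gene-level intensities of calvarial osteoblasts that the labels give as Dlk1 transgenic (Col1-Dlk1) and wild type, with 1 array of 3 combined cultures per genotype. Dlk1 (delta-like non-canonical Notch ligand) is a transmembrane protein known as a regulator of progenitor cell differentiation. The comparison asks which genes differ in level between the arrays labelled Col1-Dlk1 and wild type. The median probe-set intensity was 43.8 on the array labelled Col1-Dlk1 and 41.5 on the array labelled wild type, and the maxima were 16037 and 19077. Log2 intensities correlated across probe sets with Pearson's r = 0.92, where probe sets are not independent replicates. As a measure of spread between probe sets, the differences given by a pair of probe sets of the same gene lay a median of 0.30 log2 units apart over 6062 pairs. None of the differences below has a replicate check, since each genotype has 1 array.

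Dlk1 itself was lower on the array labelled Col1-Dlk1, against its label. The only probe set naming Dlk1 read 26.5 on that array and 306 on the array labelled wild type, a plain ratio of 11.5 and a log2 difference of -3.08 with the pseudocount. The intensity of 26.5 lies at percentile 41.1 of its array and is below the level threshold of 42.8, while 306 lies at percentile 84.9. Among level-passing genes, Dlk1 had the 20th most negative difference. Whether this probe set reads the transgene's transcript is not given in the sources used here. Every direction below is between the arrays as labelled, and it would turn around if the labels were exchanged.

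Of 6795 genes that passed the level threshold, 638 (9.39%) were at least 2-fold higher on the array labelled Col1-Dlk1, 483 (7.11%) were at least 2-fold lower, and 5674 lay between. Larger differences were mostly in one direction, with 102 genes at least 8-fold higher and 21 at least 8-fold lower. On the array without the higher signal, 375 of the higher and 236 of the lower genes read below the level threshold, so their folds depend on the pseudocount. Among called genes with several probe sets, all probe sets differed in the same direction in 384 of 394 (97.5%, exact binomial 95% interval 95.4 to 98.8%, for the sampling of genes only). Among all level-passing genes with several probe sets the share was 64.3% (62.7 to 66.0%). Called genes were chosen by the mean difference of these same probe sets, so a higher share among them is built in. Probe sets repeat the measurement on the same RNA, so this agreement describes the arrays and not the genotypes.

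**Figure D1:**
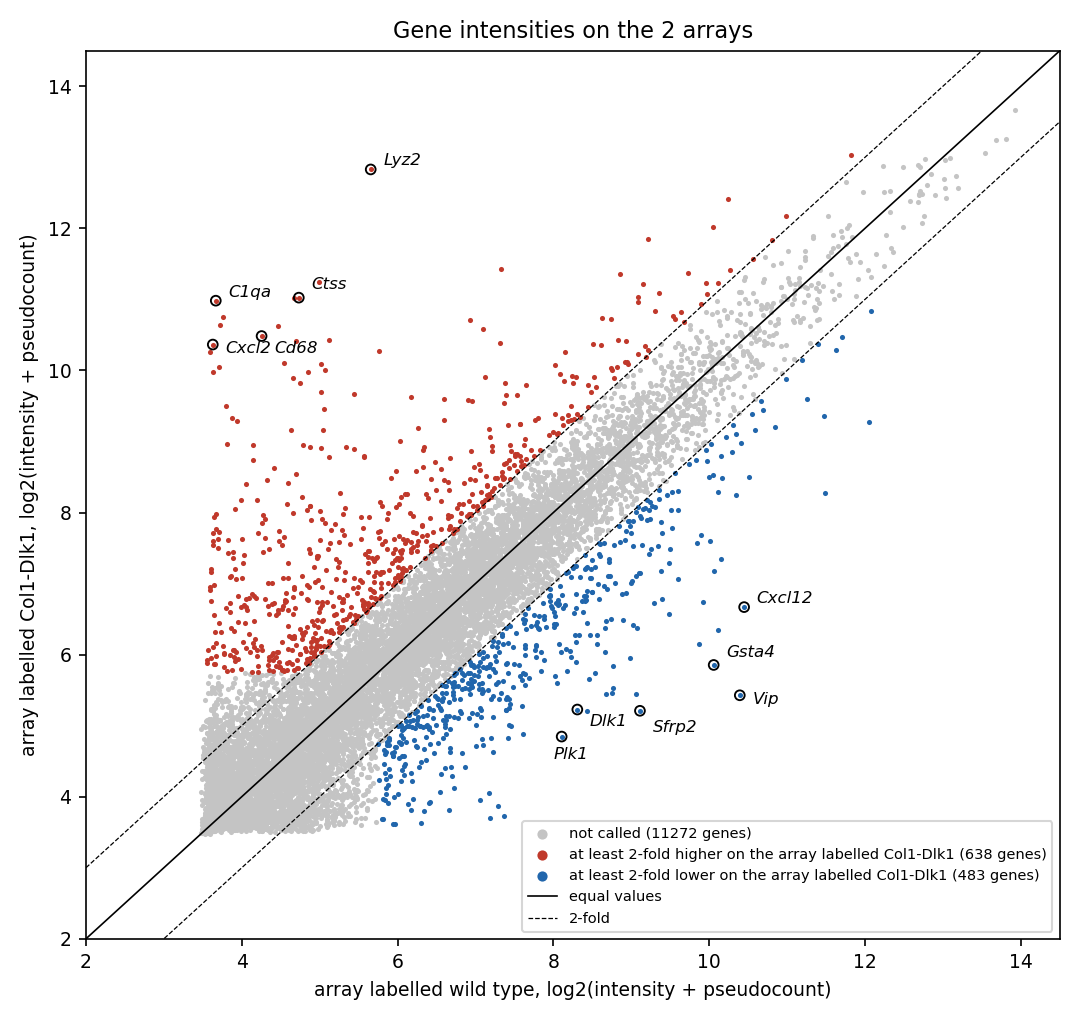
Each point is a gene, placed by log2(intensity + pseudocount) on the array labelled wild type (x axis) and on the array labelled Col1-Dlk1 (y axis), with 1 array per genotype and no error bars. The 638 higher genes include a group far above the 2-fold line with C1qa, Lyz2, Ctss and Cd68, and the 483 lower genes include Vip, Sfrp2, Cxcl12, Plk1 and Dlk1.

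Of the 12 genes with the largest positive differences, 6 are in the macrophage marker list (C1qa, Lyz2, C1qc, Mpeg1, Ctss and Cd68). C1qa and C1qc, subunits of the complement component C1q, read 2012 and 1718 on the array labelled Col1-Dlk1 against 1.74 and 2.53 on the array labelled wild type, log2 differences of 7.32 and 7.001. Lyz2, a lysozyme of myeloid cells, read 7267 against 39.4, a log2 difference of 7.17. Ms4a7 (6.92), Fcrls (6.34), Mpeg1 (6.34), the lysosomal protease gene Ctss (6.29) and the macrophage marker Cd68 (6.23) followed. Also in this group were Cxcl2, a neutrophil-attracting chemokine (6.74), Apoe, which encodes apolipoprotein E (6.68), Rgs1, a regulator of G-protein signalling (6.34), and Crct1 (6.25). These 12 genes were between 75.0-fold and 159-fold higher with the pseudocount of 10.96, which exceeds the wild-type intensity of 8 of them. With a pseudocount of 1 their log2 differences ranged from 6.79 to 9.52, so the folds depend on that choice. Crct1 read 2422 against 20.9, while none of the 10 measured epithelium and skin markers passed the level threshold on either array.

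The 12 genes with the largest negative differences were led by Vip, Gsta4 and Sfrp2, and 1 of them, Plk1, is in the cell cycle list. Vip, which encodes vasoactive intestinal peptide, read 32.1 on the array labelled Col1-Dlk1 and 1334 on the array labelled wild type, a log2 difference of -4.97. The glutathione transferase gene Gsta4 differed by -4.20, the secreted Wnt modulator Sfrp2 by -3.90, the chemokine Cxcl12 by -3.78 and Crabp1, which encodes a retinoic acid-binding protein, by -3.71. Il1rn, the antagonist of the interleukin-1 receptor, differed by -3.29 over 3 probe sets. The others were Anln (-3.77) and Prc1 (-3.61), which act in cytokinesis, Melk, a kinase gene (-3.64), Ercc6l (-3.47), the condensin subunit gene Ncapg (-3.43) and the mitotic kinase gene Plk1 (-3.26). Melk, Ercc6l and Ncapg read below 5 on the array labelled Col1-Dlk1. With a pseudocount of 1 the 12 log2 differences ranged from -5.57 to -3.63, and Melk (-5.57) and Ercc6l (-5.44) then came before Vip (-5.33).

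Macrophage markers were the list with the largest difference. Of 22 measured, 20 were at least 2-fold higher on the array labelled Col1-Dlk1, none was lower, and the other 2 were below the level threshold. The list median was 5.07 log2 units (95% interval 3.67 to 6.23), above all of the 10000 random lists. Csf1r, the receptor of the macrophage growth factor, read 1227 against 43.3, and Ptprc, the pan-leukocyte CD45 gene, read 485 against 16.7. Lyz1 and Lyz2 are near-identical paralogs, and their probe sets may share signal. Markers of other blood and vascular cells stood apart from this. None of the 14 neutrophil and mast cell, 13 lymphocyte, 8 erythroid or 14 endothelial markers was called, and only 1 of these passed the level threshold, Egfl7 at -0.88. Osteoclast markers had 2 of 11 higher, with the acid phosphatase gene Acp5 at 2.00 and the collagen-degrading protease gene Ctsk at 1.21, a list median of 0.21 and percentile 76.6.

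Cell cycle genes lay in the opposite direction. Of 29 measured, 24 were at least 2-fold lower on the array labelled Col1-Dlk1, and the list median of -2.07 (-2.39 to -1.62) was below all of the 10000 random lists. Besides Plk1, the largest differences were those of Kif20a, a mitotic kinesin (-2.91), Cdk1, the mitotic cyclin-dependent kinase (-2.82), and Aurka, a mitotic kinase (-2.79). The proliferation marker Mki67 read 105 against 478, and genes of DNA replication were also lower, with Mcm4 at -1.93 and Pcna at -1.34. The other 5 were not called lower. Ccnd1, which encodes the cyclin D of early cell cycle phases, was higher with 1673 against 746 (1.15), Ccne1 differed by 0.13, and Nusap1, Cenpe and Tyms were below the level threshold.

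Genes of osteoblast differentiation and mineralisation were mostly within 2-fold or too dim to call. Of 22 measured, 13 were below the level threshold on both arrays, 1 was higher and 1 lower. Msx2, a homeobox transcription factor of skull development, read 474 on the array labelled Col1-Dlk1 and 29.5 on the array labelled wild type (3.58), and Omd, which encodes osteomodulin, read 34.9 against 102 (-1.31). Ank, a transporter that limits mineralisation, differed by -0.98 and the matrix gene Sparc by 0.64. The type I collagen genes Col1a1 and Col1a2 differed by 0.28 and -0.18. The list median was -0.10, at percentile 18.4 of the random lists. Collagens and matrix proteins gave 4 higher and 4 lower among 31 measured, with a median of 0.14 (-0.10 to 0.54) at percentile 87.5. In this list Fmod (fibromodulin, 3.45) and Tnc (tenascin C, 2.17) were higher, and Postn (periostin, -2.78) and Fbln1 (fibulin, -1.27) were lower.

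Matrix proteases and their inhibitors had 8 of 23 measured genes higher and none lower, with a median of 0.58 (0.38 to 1.12) at percentile 99.98. The largest differences were those of Mmp13, the collagenase of bone cells, which read 89.7 against 3.01 (2.85), Mmp23 (2.63), the lysosomal protease gene Ctsb (2.51) and Mmp10 (1.55). The macrophage marker median of 5.07 lay in the same direction. Without the members of the macrophage and osteoclast lists, 7 of 21 genes were higher, none was lower and the median was again 0.58. This took out only Ctsk and Mmp9, both in the osteoclast list, so it cannot show whether macrophage RNA bears on the other proteases.

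Regulators of osteoclast formation that osteoblasts produce were split, with 5 of 22 measured genes higher and 3 lower and a median of -0.15 at percentile 13.0. The cytokine genes Tnf (242 against 1.71, a log2 difference of 4.32) and Il1b (132 against 29.3, 1.83) and the adhesion gene Icam1 (4.09) were higher, together with 20 of 22 macrophage markers, while Cxcl12 was lower. Il6 differed by 0.63, the growth factor gene Csf1 by 0.50 and Tnfrsf11b, the decoy receptor osteoprotegerin, by -0.86, all within 2-fold. Chemokines had 9 of 25 higher and 2 lower, with a median of 0.59 (0.06 to 2.13), above all random lists. Next to Cxcl2, Ccl3 (3.82) and Cxcl16 (3.61) were the chemokines with the largest positive differences, and these too lay in the direction of the macrophage markers. NF-kB targets and regulators had 3 of 24 higher and 2 lower and a median of 0.03 at percentile 53.7. Apart from Icam1, their largest differences were those of Cxcl5 (-1.63), Nfkbiz (1.41) and Rel (-1.37).

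Complement genes had 7 of 15 measured members higher and 1 lower, with a median of 1.14 (0.37 to 4.53), above all random lists. C1qb (5.57) and the anaphylatoxin receptor gene C3ar1 (4.53) stood next to C1qa and C1qc. The 3 C1q genes are also in the macrophage list, and without them 4 of 12 were higher and the median was 0.55. The 4 were C3ar1, Cfp (3.92), C5ar1 (1.57) and Cd59a (1.14). Only genes of the marker lists were taken out, so the removal cannot show which cells made the other transcripts. Interferon-stimulated genes were lower on the array labelled Col1-Dlk1 in 7 of 22 cases and higher in 2, and their median of -0.67 (-1.40 to -0.01) lay below all random lists. Iigp1 (-2.26), Ifit1 (-2.20) and Usp18 (-2.06) were lower, and Oas2 (2.06) was higher.

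Genes of cholesterol synthesis were lower in 9 of 15 measured cases and higher in none, with a median of -1.41 (-2.20 to -0.62), below all random lists. The macrophage markers, with a median of 5.07, differed between the same arrays. Stard4, a sterol transporter, differed by -2.59, and the synthesis enzymes Idi1, Sqle and Hmgcs1 differed by -2.47, -2.20 and -2.20. Of the adipocyte genes, 4 of 18 were higher and 2 lower, with a median of 0.20 at percentile 88.5. Lpl, the lipoprotein lipase that macrophages also make, read 819 against 21.5 (4.68), and the transcription factor gene Cebpa (2.73) and the lipid droplet gene Plin2 (1.53) were higher, while the fatty acid desaturase gene Scd1 was lower (-1.69). Cartilage genes had 1 of 20 lower, Sox9 at -1.35, and none higher, while 16 were below the level threshold and could not be called. Comp (-0.91), Prg4 (0.56) and Col2a1 (0.41) were within 2-fold, and the median was -0.10 at percentile 17.0.

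Among signalling pathways, the IGF list had the most members higher in proportion, with 6 of 16 higher and 1 lower and a median of 0.51 (-0.17 to 1.82) at percentile 99.7. Igf1, a growth factor of bone and also of macrophages, read 434 against 36.4 (3.23), the protease gene Pappa 461 against 69.2 (2.56) and Igfbp5 259 against 52.2 (2.10), while Igfbp6 was lower (-1.83). Macrophage markers were higher on the same array. The Notch list had none of 26 higher and 1 lower, Dlk2 at -1.34, a close paralog of Dlk1, while 15 were below the level threshold and could not be called. The Notch list median was 0.30 (-0.15 to 0.57) at percentile 97.9, with Notch2 (0.69), Numb (0.68) and Notch3 (0.66) within 2-fold. Wnt pathway genes had 5 of 36 higher, 3 lower and 19 below the level threshold, and a median of -0.05 at percentile 25.2. Dkk3 (2.79) and the receptor gene Fzd8 (1.43) were higher and, besides Sfrp2, the receptor gene Fzd6 (-1.54) was lower. BMP and TGF-beta genes had 5 of 35 higher and 3 lower and a median of 0.27 (-0.24 to 0.48) at percentile 98.2. Inhba, the activin subunit gene (1.99), the BMP antagonist gene Grem1 (1.57) and Id2 (1.35) were higher, and Id4 (-1.83) was lower.

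Fibroblast and suture progenitor genes had 2 of 19 higher and 3 lower, with a median of 0.21 at percentile 90.4. The stem cell antigen gene Cd34 (-2.43), the growth factor receptor gene Pdgfra (-1.81) and Efemp1 (-1.43) were lower and the TGF-beta co-receptor gene Eng (1.99) was higher. Imprinted growth genes had 3 of 19 lower and none higher, namely Mest (-2.13), Peg3 (-2.10) and Cdkn1c (-1.22), with a median of 0.05 at percentile 61.3. Impact differed by 0.62. Smooth muscle and pericyte markers had 2 of 14 lower, Smtn (-2.11) and Mcam (-1.98), and none higher, with a median of -0.35 at percentile 2.72. Cspg4 differed by -0.79. Nerve and glia markers had 1 of 12 lower, Stmn2 at -1.68, with Ncam1 at 0.90 and Tubb3 at -0.52, and a median of -0.30 at percentile 8.68. Skeletal muscle markers had none of 20 called, and only Acta1 passed the level threshold, at 0.88.

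Immediate early genes, which respond to cell handling as well as to growth factors, differed in both directions. Of 26, 6 were higher and 7 lower, and the median was -0.17 at percentile 9.10. Fos (3699 against 581, 2.65) and Zfp36 (2.05) were higher, and Egr2 (-3.04) and Nr4a1 (-2.12) were lower. Hypoxia and glycolysis genes had 1 of 19 higher, Adm at 2.59, and 2 lower, Vegfa at -1.41 and Slc2a1 at -1.03, with Ddit4 at 0.86 and a median of 0.19 at percentile 88.6. Of the sex-linked genes, 4 were measured and only Eif2s3y passed the level threshold, at 77.1 against 114 (-0.50). Among the RNA quality controls, the ratio of the 3′ to the 5′ probe set was 0.89 on the array labelled Col1-Dlk1 and 0.82 on the array labelled wild type for Gapdh, and 1.53 and 1.29 for beta-actin. Some other mouse control probe sets differed more between the arrays than those for Gapdh and beta-actin, but not all, and AFFX-MURINE_B2_at had a ratio of 1.08. The middle probe set for 18S ribosomal RNA read 3.66 on the array labelled Col1-Dlk1 and 43.5 on the array labelled wild type (-1.90), and the 4 for pyruvate carboxylase had ratios between the arrays of 1.44 to 5.46, the highest from intensities of 32.8 and 6.00. The ratios between the arrays of 9 spiked hybridisation controls ranged from 0.71 to 1.30.

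**Figure D2:**
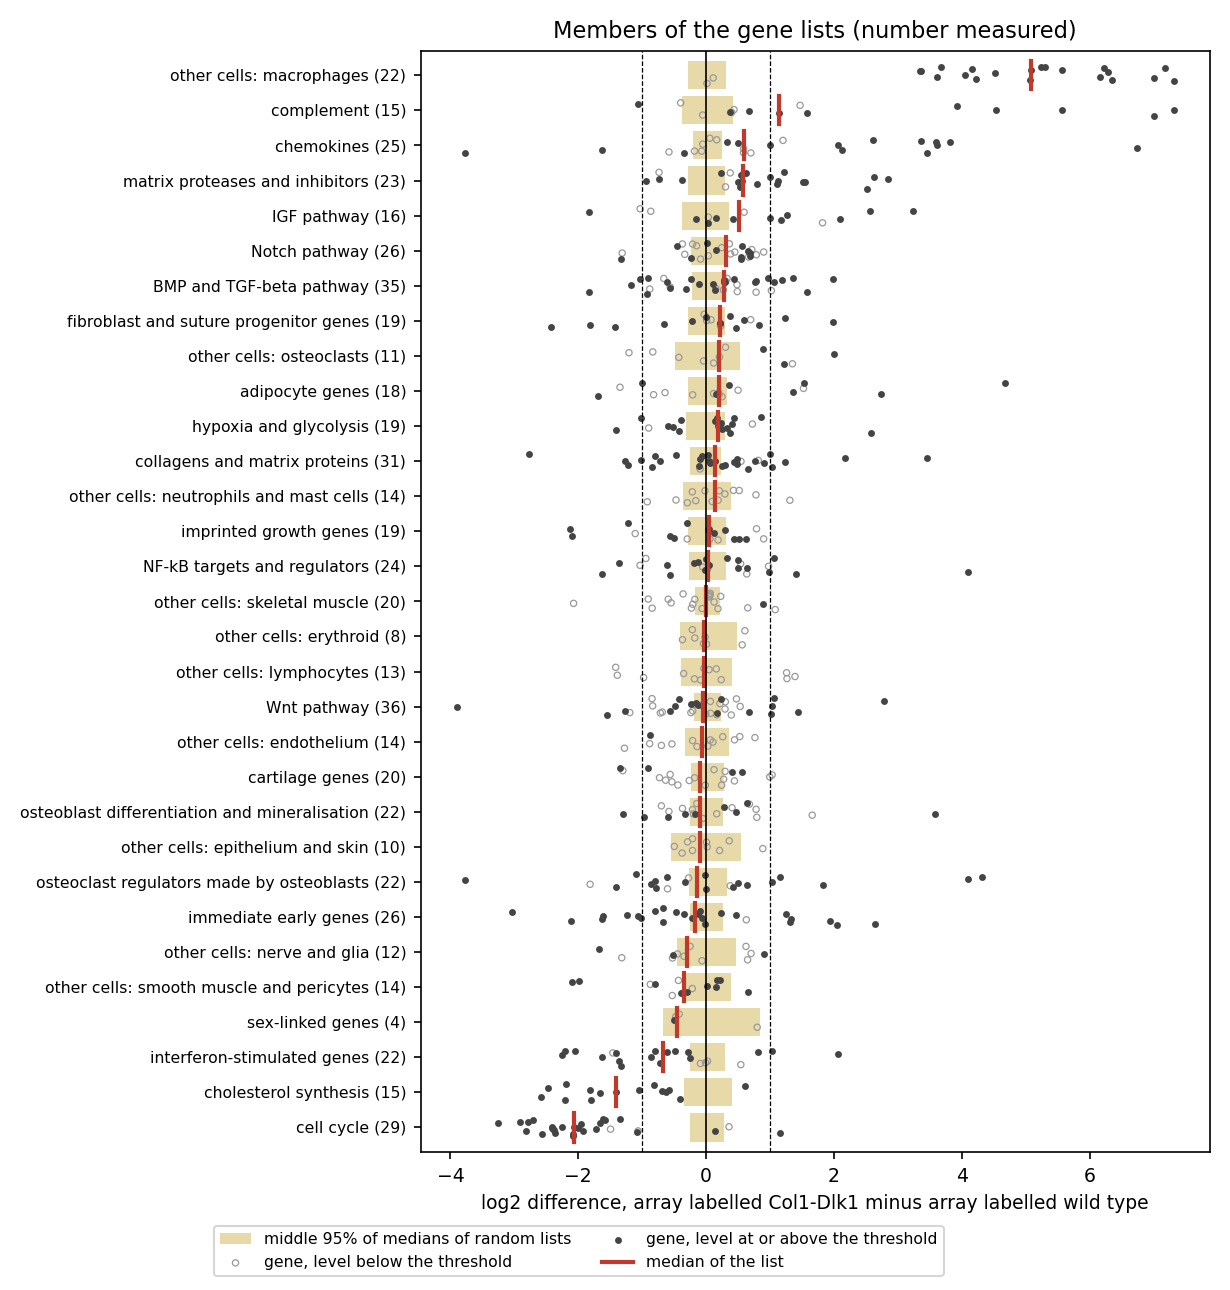
Log2 differences (x axis, array labelled Col1-Dlk1 minus array labelled wild type) of the measured members of each gene list fixed before the data were examined, ordered by list median (y axis), with 1 point per gene, a bar for the median and a band for the middle 95% of medians of 10000 matched random lists. Macrophage markers stand at the top with a median of 5.07, and cell cycle genes at the bottom with a median of -2.07.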

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

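The rules for groups of samples could not be applied with 1 array per genotype, and the signals below come from probe sets that no comparison uses. The mouse repeat-element control probe set AFFX-MURINE_b1_at read 2897 on the array labelled Col1-Dlk1 against 1442 on the array labelled wild type, a ratio of 2.01. Among 953 level-passing probe sets that name several genes or none, 88 were at least 2-fold higher on the array labelled Col1-Dlk1 and 104 at least 2-fold lower.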

How the results depend on the processing

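No paired analysis was possible because each genotype has 1 array, and no replicate could be left out. The 638 higher and 483 lower genes became 417 and 287 with the median as pseudocount, 1307 and 1154 at 1.5-fold, 327 and 204 at 3-fold, 331 and 236 with the level threshold at the 75th percentile, and 1171 and 1042 when probe sets were counted in place of genes. Without a level filter 772 genes were lower. The other settings moved these counts by no more than 1.5 times (451 to 944 higher, 371 to 639 lower). All 24 genes with the largest differences remained called in the same direction under the 3 scalings. The same held for the pseudocount of 1 and the probe set with the highest mean level. With the pseudocount of 1, 21 of them moved by more than 0.24 log2 units. That value is the SD between probe sets of the same gene on these arrays, and it holds no error of labelling or hybridisation. The Dlk1 difference was -3.48 with a pseudocount of 1, and the share of called genes whose probe sets agreed was 94.6%. Of 184 alternatives of 31 list medians, 3 left the median's interval: skeletal muscle over its level-passing member (0.88), and sex-linked genes with median centring (-0.51) and with a pseudocount of 1 (-0.56). Some of these intervals are wide, so a median inside its interval can still have moved much. Over level-passing members alone the median was 2.13 in place of 0.59 for chemokines and 2.75 in place of 1.14 for complement. It was 0.86 in place of 0.20 for adipocyte genes and 1.00 in place of 0.51 for the IGF list. No scaling shifted the median of all genes by over 0.1. No detection calls were used, so the folds of dim genes depend on the pseudocount. The removal of macrophage and osteoclast markers from the lists was chosen after seeing the data.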

Other observations

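The tests of the second macrophage list and of the patterning genes were set before their values were seen, though the rule of the latter was changed and put back afterwards. The other tests here were chosen after the results were seen, and the NF-kB list, first read alone as arguing against its explanation, was last read together with chemokines. Lysosome genes, a list added after seeing the data, were at least 2-fold higher on the array labelled Col1-Dlk1 in 12 of 23 measured cases and lower in none, with a median log2 difference of 1.14 (0.55 to 1.32). Lgmn (2.15), Ctsd (1.97), Gm2a (1.84) and Tpp1 (1.74) differed most, in the direction of the macrophage markers.

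Genes listed for patterning of the developing head differed in both directions. The list, added after 5 of its members had been seen to be lower, had 15 level-passing members. Of these, 8 were lower on the array labelled Col1-Dlk1, among them Crabp1 (-3.71), Capn6 (-3.22), Tfap2b (-3.12) and Dlx2 (-2.79). The 4 higher members included Zic1 (2.13) and Six2 (1.98). Crabp1 is in the list though it encodes a retinoic acid-binding protein. Msx2 (3.58), a homeobox gene of skull development, is in the osteoblast list and not in these counts. None of 22 measured Hox genes passed the level threshold. A hypothesis is that the cultures may differ in the regions of the skull they came from. It predicted that at least 30% of the members whose values had not been seen would be lower. Of these 10 genes, 3 (30%) were lower, which met the bound exactly, and 4 were higher. Their median difference was 0.42, in the direction opposite to the prediction. After these values were seen the rule was changed to ask also for more lower than higher genes, which failed, and was then put back to the bound as first written, so the result rests on the choice of rule. The 7 that differed by at least 2-fold in either direction compare with 16.5% of all level-passing genes, but the prediction did not cover that share. The test rests on 10 genes with 1 array per genotype, and genotype and sorting stay open as untested explanations.

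Macrophage markers were higher on the array labelled Col1-Dlk1, 20 of 22 by at least 2-fold. Scaling of the arrays is argued against by the size of the difference, since the list median stayed between 5.01 and 5.11 under the 3 scalings. That 20 were higher under each of them could be foreseen from this size and adds no separate evidence. An inflammatory response of the osteoblasts stays open, since the lists tested do not decide it. Of the measured NF-kB list 12.5% was higher, with members in both directions. But 9 of 25 chemokines were higher too, with Cxcl2 at 6.74 and Ccl3 at 3.82, as were Tnf (4.32), Icam1 (4.09) and Il1b (1.83). Neither list holds markers such as Ptprc (485 against 16.7) or Csf1r (1227 against 43.3), so neither shows which cells made those transcripts. A candidate source is RNA of macrophages within the cultures: in a second list of macrophage and pan-leukocyte genes 67.6% were at least 2-fold higher (23 of 34, none lower), with Cd53 at 1656 against 111 and Cd48 at 200.4 against 2.12. A sort for Dlk1-positive cells would be expected to remove macrophages, and whether their number differed by genotype, by sorting or by culture stays open and untested.

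Cell cycle genes were lower on the array labelled Col1-Dlk1, with a median of -2.07. Dilution of osteoblast RNA by RNA of other cells would lower matrix genes alike, but the collagen and matrix list had a median of 0.14. A level-dependent scaling difference is argued against by the median of -2.06 (-2.38 to -1.61) after loess. Culture density, sorting and genotype stay open as untested explanations.

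Dlk1 was lower on the array whose label names its overexpression. Dilution by RNA of other cells is argued against by the collagen and matrix list, whose lower 95% bound was -0.10. What stays open is an exchange of the array labels, which could give the difference of -3.08, or a probe set that does not read the transgene, together with a lower level of native Dlk1 in those cultures. With 1 Dlk1 probe set and 1 array per genotype these cannot be told apart. The array with low Dlk1 is also the one with 20 of 22 macrophage markers higher, though its protocol names a sort for Dlk1-positive cells. An exchange of labels could bear on both patterns and an unread transgene on Dlk1 alone, but neither was tested. Under exchanged labels the higher macrophage markers would lie on the array of wild-type cells, and 638 genes would be lower and 483 higher with Dlk1.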
